A study of Mus musculus with 4 samples.

How the data were processed

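The series measured messenger RNA in single CD45-positive cells from B16-F10 tumours, a mouse melanoma line grown in syngeneic C57BL/6 mice. Adar1, encoded by Adar, is an adenosine deaminase that edits double-stranded RNA. Per the labels, 2 libraries came from Adar1-null tumours and 2 from control tumours. Cells were implanted with matrigel and tumours taken on day 14. A digestion of 10 min at 37 °C used collagenase P together with DNase I. Leukocytes were enriched on a density gradient and by magnetic selection for CD45, and libraries were made with the droplet-based 10x 3′ v2 kit, which counts molecules through unique molecular identifiers (UMIs). The selection was not complete, since melanoma-like cells made up part of each library. Shares of cell classes describe the selected suspension and not the tumour.

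The authors deposited one matrix of whole-number UMI counts per gene and cell for all 4 libraries together, with no normalization. Per the submitters' processing notes, Cell Ranger, Seurat 2.2.0 and the mouse build mm10 were used. The version of Cell Ranger, the gene annotation, the aligner settings and any filter on cells or doublets before deposit are not given in the sources used here. Each barcode in the deposited list carries a library name that shows its group. The names carry no replicate number, so the libraries are called S1 and S2 (Adar1-null) and S3 and S4 (control), and S1 to S4 pair nothing across groups. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

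The matrix held 8838 barcodes and 27998 genes, of which 19218 had a UMI. The lowest UMI total of any barcode was 3961, and it lay between 3961 and 4373 in each library, so shallow cells had been removed before deposit. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept here. This removed 161 barcodes, of which 16 fell under the gene minimum and 148 were over the mitochondrial maximum. Scrublet (scanpy 1.11.5, expected rate 0.02) scored doublets per library. Its automatic thresholds lay between 0.137 and 0.240 and marked 3 to 24 cells per library, so a common score of 0.1 was set after seeing the scores, which removed 118 cells (1.36%). Kept were 8559 cells.

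Cells were clustered without batch correction. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 were used (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Interferon, MHC, cell cycle, dissociation, mitochondrial and antigen-receptor genes were left out of the clustering, so that these genes were not used to define the clusters. Other genes, among them Arg1 and Spp1 of the macrophage lists, could define clusters and were also tested within them. Clusters were called by a class name with the suffix "-like" only from marker lists fixed before the data were examined. A name needed at least 3 markers detected in at least 10% of the cluster's cells. Where the 10 leading genes of a cluster held more markers of another class, the cluster took that class if at least 2 such markers led it, and otherwise stayed unnamed. Free RNA in the droplets adds UMIs of abundant transcripts to all cells, and no correction for it was applied.

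UMI counts were summed per library and class, since cells are not replicates. A class or cluster was tested where every library held at least 50 cells. Sums were compared with edgeR 4.0.16 (R 4.3.3): TMM normalization, the default filter on low counts, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05, with no covariates. DESeq2 1.42.0 was an alternative. The values given are CPM per library (UMI counts scaled to a common library total), log2 changes of Adar1-null over control with their standard errors, and means ± SD over n = 2 libraries. A gene was called separated where both Adar1-null libraries lay on the same side of both control libraries, which chance gives for 33.3% of genes. Numbers of cells per class were compared with the same edgeR test on the total of kept cells, and with an exact two-sided permutation test, whose smallest possible p is 0.333 with 6 splits. Single shares carry exact binomial 95% intervals, which cover counting error only. Differences in response between classes were tested as an interaction with the library as a block.

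The 24 gene lists were fixed before the data were examined: type I interferon-stimulated, interferon-gamma-induced, MHC class I and MHC class II presentation, cytotoxic effector, T cell inhibitory receptor and exhaustion, naive and memory T cell, cell cycle, alternatively activated and suppressive macrophage, inflammatory macrophage, complement C1q and tissue-macrophage, chemokine, hypoxia and glycolysis, oxidative phosphorylation, lipid handling, dissociation and immediate-early, double-stranded RNA sensing, unfolded protein response, and TNF and NF-kB response genes, and melanocyte, erythroid, fibroblast, endothelial and neutrophil transcripts. The erythroid list held too few measured genes to be tested within any class. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. None of the lists called with the preset correlation held with an estimated correlation or with fry, in any class. Each count of list members past the threshold adjusted over the list alone stands beside that over all genes.

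Genes were named by a rule fixed before the data were examined: Adar; up to 10 genes per direction and class past the threshold, with a mean of at least 50 CPM, separated between the groups, without Gm-numbered, Rik or receptor-segment genes; up to 4 members per list by smallest adjusted p; and 27 fixed genes, among them Isg15, Cxcl9, Cxcl10, Cd74, Gzmb, Pdcd1, Arg1 and Il1b. Some genes within this rule or the lists are not reported here. A gene outside this rule is said to have been chosen after its values were seen. Gene positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names. Reads shared between genes were estimated as the percent of 25-base words in the last 300 bases of a gene's transcripts that occur in another gene.

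The steps were tested on simulated counts drawn with the means, spread and library sizes of the real counts, with 200 genes changed. In the T cell sums, 62% of genes changed by a log2 of 1 and 91% of those changed by 2 were recovered, and 14 of 167 calls were false. In cluster 3, where S2 held the fewest cells, the shares were 12% and 83%, and 8 of 103 calls were false. In melanoma-like cells 26 of 200 calls were false and in the monocyte-like cluster 24 of 146. CD8 T cell-like cells gave 12 false calls of 161 and cluster 7 gave 13 of 151. In every class and cluster and in the whole infiltrate the false share was more than the threshold of 0.05 allows. The list test at the preset correlation called the moved list in the T cell sums and 0 of 20 unmoved lists, but it called 3 of 21 unmoved lists in melanoma-like cells, 2 of 22 in the whole infiltrate and 2 of 21 in the monocyte-like cluster. In the T cell sums, with an estimated correlation the moved list had adjusted p = 0.135, so that test had little power with 4 libraries. Correlation between genes was not among the properties taken from the real counts. There the estimated correlation of the type I interferon list was 0.58 in T cell-like and 0.85 in macrophage-like cells. It differed between lists, at -0.05 for inhibitory receptor and exhaustion genes in T cell-like cells. The simulation thus does not show how the preset performs on strongly correlated lists. For shares, a class moved 4-fold was called in 91% of 100 simulations, and unmoved classes in 0.9%.

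Alternatives tried were other size factors, DESeq2, no filter on low counts, doublets kept, all barcodes kept, Leiden resolutions 0.5 and 2.0, equal numbers of cells per library, TMM on cell numbers, a denominator of immune cells, and leaving out each library. Chosen after seeing the data were clustering with the response genes included, immune cells only for the whole infiltrate, and the largest melanoma-like cluster only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.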

Results

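Libraries S1, S2 and S3 held similar numbers of deep cells, and S4 held more. S1 and S2 (Adar1-null) gave 1938 and 1929 kept cells with medians of 7916.5 and 7588 UMIs, and S3 and S4 (control) gave 1943 and 2749 with 8813 and 7854. Summed over all cells, the closest pair of libraries was S1 and S3, of different groups, at a chi-square per gene of 16.5. S1 and S2 were at 19.2 and S2 and S3 at 21.3. S4 stood apart from all 3 others, at 64.0 from S1, 87.9 from S2 and 53.6 from S3.

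Monocytes and macrophages dominated the infiltrate, followed by T cells and residual melanoma cells. Among 20 clusters, 7 were monocyte- or macrophage-like. They were led by Vcam1 and Lpl (cluster 2), Cxcl3, Mmp12, Arg1 and Spp1 (cluster 3), Chil3 and Il1b (cluster 4, monocyte-like), Sepp1 and Cbr2 (cluster 5), Ccl7 and Ccl12 (cluster 7), Cd300e (cluster 11) and Retnla and Ear2 (cluster 13). CD8 T cell-like cells formed clusters 6 (Gzmf, Gzmd) and 8 (Ccl5, Cxcr6), and regulatory T cell-like cells cluster 10 (Tnfrsf4, Ikzf2). Natural killer, conventional dendritic cell 1 and 2, migratory and plasmacytoid dendritic, fibroblast and endothelial cell-like clusters were also found. Cluster 12 (Cd209f, Cd209g) stayed unnamed, and no cluster was B cell-, neutrophil- or gamma-delta T cell-like at the resolution used. At a Leiden resolution of 2.0, a neutrophil-like cluster of 178 cells and an erythroid-like cluster of 31 cells were named.

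Adar was detected at similar levels in all libraries. In the whole infiltrate its level was 13.7 and 16.0 CPM in S1 and S2 and 15.4 and 14.8 CPM in S3 and S4 (log2 change -0.09 ± 0.11). In melanoma-like cells, the only cells of the tumour line, 98, 121, 103 and 149 UMIs were counted in S1 to S4, and the log2 change was -0.15 ± 0.16 (adjusted p = 0.9999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Monocyte- or macrophage-like cells gave 18.3, 19.9, 18.6 and 17.0 CPM, and CD8 T cell-like cells 11.8, 15.8, 14.5 and 9.95 CPM. Adar lies on chromosome 3 at 89715022 to 89753446. Counts of 3′ tags check nothing about the deletion, since a small edit in the coding sequence can leave the 3′ end of the transcript in place.

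T cells carry antitumour killing and regulation, and macrophages can restrain it, so their shares were compared first. T cell-like cells made up 19.5 ± 0.905% of Adar1-null and 12.4 ± 2.99% of control cells (log2 ratio 0.65). Monocyte- or macrophage-like cells made up 52.6 ± 0.393% and 62.4 ± 5.18% (log2 ratio -0.25), and melanoma-like cells 16.8 ± 2.58% and 12.7 ± 1.43% (0.40). Migratory dendritic cell-like cells were at 2.09 ± 0.688% and 1.23 ± 0.449% (0.78). The unnamed cluster 12 was at 0.362 ± 0.218% and 3.19 ± 2.90% (-3.13), with 10, 4, 22 and 144 cells in S1 to S4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11 classes, none of these passed (adjusted p = 0.483, 0.706, 0.524, 0.483 and 0.224), although in each both Adar1-null libraries lay on the same side of both control libraries. Without S3, the unnamed cluster 12 was at -3.83 and passed the same test (adjusted p = 0.00505). Natural killer cell-like (2.25 ± 1.14% and 1.76 ± 1.66%), conventional dendritic cell 2-like (3.65 ± 0.634% and 3.10 ± 1.44%) and fibroblast-like cells (0.647 ± 0.331% and 0.745 ± 0.181%) overlapped between the groups. Permutation p was 0.333 for T cell-like, macrophage-like and melanoma-like cells, the smallest value possible.

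**Figure D1:**
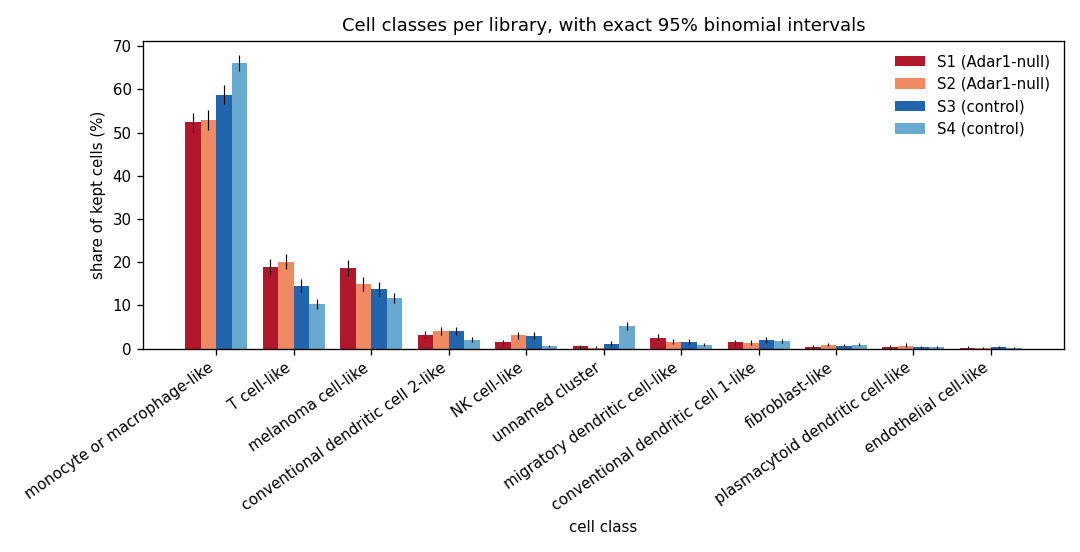
Share of kept cells (%) in each cell class for S1 and S2 (Adar1-null) and S3 and S4 (control). Bars are single libraries, and lines are exact 95% binomial intervals, which cover counting error only.

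Within the T cells, the regulatory share was higher in both Adar1-null libraries, at 24.1% and 18.0% against 15.2% and 13.03%. The means were 21.1 ± 4.29% and 14.1 ± 1.53% (log2 ratio 0.57 ± 0.21, adjusted p = 0.106 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without S2 the ratio was 0.77 and passed the test, and without S1 it was 0.35 and did not. Among monocytes, macrophages and dendritic cells, cluster 5 made up 3.11 ± 2.11% and 20.9 ± 15.3% (-2.75, adjusted p = 0.0530 by the same test) and cluster 12 0.597 ± 0.362% and 4.26 ± 3.67% (-2.83, adjusted p = 0.0530). The markers of cluster 5, such as Folr2, mark tissue-resident macrophages. In S4, cluster 5 held 667 cells, against 54, 19 and 133 in S1, S2 and S3. The monocyte-like cluster 4 lay at 22.6 ± 8.67% and 11.6 ± 5.10% (0.97, adjusted p = 0.559), and cluster 11 at 6.61 ± 5.12% and 2.30 ± 2.65% (1.54, adjusted p = 0.416). Without S3, clusters 5 (-3.35), 12 (-3.50) and 11 (3.92) passed the test. Without S4, clusters 5 and 12 were at -1.69 and -1.47, and without S2 cluster 11 was at 0.39, none of which passed.

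Tissue-macrophage transcripts had lower estimates in the Adar1-null whole infiltrate. Ccl8, a monocyte chemoattractant, was at 1224 ± 177 CPM in Adar1-null and 2516 ± 224 CPM in control libraries (log2 change -1.11 ± 0.14), and C1qa, a complement subunit made by macrophages, at 1231 ± 16.6 and 1881 ± 306 CPM (-0.68 ± 0.14). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13465 genes passed, and DESeq2 called 6 higher and 87 lower. At unadjusted p under 0.05, 409 were higher and 828 lower, 1237 in all against 673.25 expected by chance. Without S3, 118 genes passed, and 0 passed without S1, S2 or S4. Both Adar1-null libraries lay on the same side of both control libraries for 49.0% of genes, against 33.3% by chance. Adjusted over the list alone, 7 of 22 complement C1q and tissue-macrophage genes were lower, led by Ctsb (-0.58), C1qa, C1qb (-0.66) and C1qc (-0.74), and 0 over all genes. This list had a median of -0.64 (camera, adjusted p = 1.3e-07 with the preset and adjusted p = 0.765 with an estimated correlation). Within monocyte- or macrophage-like cells its median was -0.15 and the list was not called (adjusted p = 0.0525, and adjusted p = 0.625 with an estimated correlation), with C1qa at -0.16 ± 0.15. In the monocyte-like cluster it was at 0.11 (adjusted p = 0.181, and adjusted p = 0.798 with an estimated correlation).

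The other lists in the whole infiltrate were called with camera's preset correlation only, or not at all. Alternatively activated and suppressive macrophage genes, some of which, such as Folr2 and Cd163, lead clusters 5 and 12, had a median of -1.12 with 4 of 30 positive (camera, adjusted p = 8.71e-08, and adjusted p = 0.765 with an estimated correlation). Chemokines had a median of -0.46 (adjusted p = 0.000783, and adjusted p = 0.765 with an estimated correlation), and Ccl8 alone was lower adjusted over the list alone, and 0 over all genes. Hypoxia and glycolysis genes were at -0.20 (adjusted p = 8.25e-06, and adjusted p = 0.765 with an estimated correlation). Melanocyte transcripts were at 0.19 (adjusted p = 0.000209, and adjusted p = 0.765 with an estimated correlation), with Pmel at 0.38 and Mlana at 0.25. Cell cycle genes were at 0.13 (adjusted p = 2.12e-05, and adjusted p = 0.902 with an estimated correlation), with Dut at 0.26 and Mki67 at 0.21. Dissociation and immediate-early genes, which handling can induce, were at -0.28 (adjusted p = 0.0316, and adjusted p = 0.902 with an estimated correlation). Fibroblast (-0.34), endothelial (-0.30) and neutrophil transcripts (-0.92) were not called (adjusted p = 0.313, 0.399 and 0.113, and adjusted p = 0.902 with an estimated correlation for all 3). The list of lipid handling genes was not called (11 of 22 positive, adjusted p = 0.744, and adjusted p = 0.902 with an estimated correlation), but 3 members, among them Fdps (0.62) and Idi1 (0.47), were higher adjusted over the list alone, and 0 over all genes. In cytotoxic effector genes the median was 0.10 but the mean -0.31, and the list was not called. Lists called numbered 8, and 15 without S2 and 16 without S3.

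Type I interferon-stimulated genes answer interferon alpha and beta, which double-stranded RNA left unedited in the absence of Adar1 can induce. In monocyte- or macrophage-like cells 51 of 54 had a positive log2 change, with a median of 0.61 (camera, adjusted p = 2.15e-17, and adjusted p = 0.625 with an estimated correlation). Isg15, a ubiquitin-like modifier, was at 427, 978, 424 and 220 CPM in S1 to S4 (1.12 ± 0.49), and Irf7, which amplifies interferon production, had an estimate of 1.07 ± 0.39. Isg20, the list's first member by p, was at 48.7 ± 24.3 and 18.9 ± 4.24 CPM (1.36 ± 0.38). No member passed adjusted over the list alone or over all genes, and 18 members were separated upward and 1 downward. Of all genes tested there, 34.7% were separated in either direction, about as often as in the list. Separated upward were 32 of 48 members in T cell-like cells, 29 of 53 in the monocyte-like cluster and 30 of 54 in cluster 7, and 0 downward in these. Clusters 2 and 3 gave 21 of 53 and 16 of 54. CD8 T cell-like cells gave 20 of 43 and conventional dendritic cell 2-like cells 19 of 44, each with 1 downward. The whole infiltrate gave 5 of 54 and melanoma-like cells 3 of 46, each with 2 downward. Of all genes, between 31.1% and 37.0% were separated in either direction in the other T cell and myeloid units. In monocyte- or macrophage-like cells the medians after centring each gene were -0.08 and 0.69 in S1 and S2 and 0.00 and -0.63 in S3 and S4. S2 and S4 thus lay apart, while S1 and S3 did not. Over the 8 T cell and myeloid units the median difference was between 0.92 and 1.48 for S2 less S4 and between -0.15 and 0.20 for S1 less S3.

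**Figure D2:**
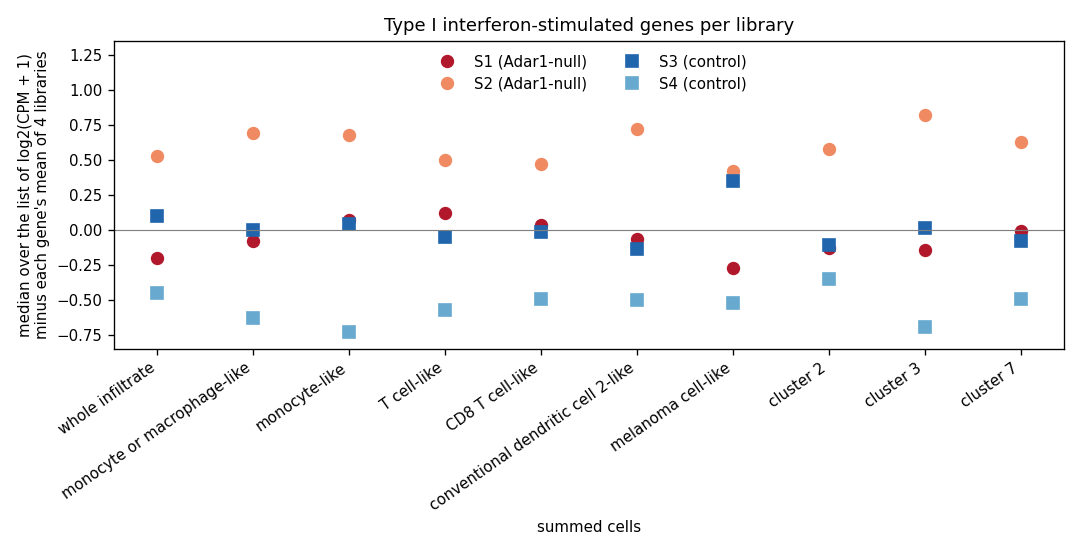
Median over type I interferon-stimulated genes of log2(CPM + 1) less each gene's mean of 4 libraries, by class or cluster. Points are single libraries, circles S1 and S2 (Adar1-null) and squares S3 and S4 (control).

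Macrophage activation lists were called in the same cells with camera's preset correlation only. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 10948 genes passed, with 204 higher and 325 lower at unadjusted p under 0.05, and DESeq2 called 4 and 17. The 529 genes at unadjusted p under 0.05 were fewer than the 547.4 expected by chance. Without S3, 86 genes passed, and without any other library 0. Interferon-gamma-induced genes (0.59, adjusted p = 1.07e-07), MHC class I presentation (0.44, adjusted p = 2.02e-06) and MHC class II presentation (0.56, 13 of 13 positive, adjusted p = 2.77e-05) were called by camera, all with adjusted p = 0.625 with an estimated correlation. The MHC class II list rested on S4, since without it the median was 0.0857 and the list was not called (adjusted p = 0.425). In S1 to S4, H2-Ab1 was at 3434, 4330, 3635 and 1316 CPM and Cd74 at 5272, 6849, 5515 and 2362 CPM. Inflammatory macrophage genes were at 0.36 (adjusted p = 0.000102, and adjusted p = 0.625 with an estimated correlation), with Il12b, an interleukin-12 subunit, at 3.23 and Il1b at 1 ± 0.32. Alternatively activated and suppressive macrophage genes were at -0.68 (adjusted p = 2.13e-06, and adjusted p = 0.625 with an estimated correlation), led by the scavenger receptor Marco (-2.77 ± 0.51). Double-stranded RNA sensing genes were at 0.28 (adjusted p = 0.00342), TNF and NF-kB response genes at 0.21 (adjusted p = 0.00215) and lipid handling genes at 0.29 (adjusted p = 0.0157), each with adjusted p = 0.625 with an estimated correlation. Oxidative phosphorylation genes were at 0.10 (adjusted p = 0.0157, and adjusted p = 0.763 with an estimated correlation) and cell cycle genes at -0.15 (adjusted p = 0.0492, and adjusted p = 0.779 with an estimated correlation). Neither kept its sign, with oxidative phosphorylation at -0.0619 without S4 and cell cycle at 0.16 without S3. Cytotoxic effector genes were at 0.79 (adjusted p = 0.000418, and adjusted p = 0.625 with an estimated correlation), led by Nkg7 (1.01 ± 0.25), and free RNA from T cells can add these. The largest macrophage cluster was cluster 2 in S1 (289 cells) and S3 (306), cluster 4 in S2 (337) and cluster 5 in S4 (667).

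Arg1 and Spp1, both linked to suppressive macrophages, were called lower in cluster 7, the Ccl7 and Ccl12 cluster. Arg1, which depletes arginine, was at 210 ± 4.79 CPM in Adar1-null and 943 ± 243 CPM in control libraries (log2 change -2.14 ± 0.19, adjusted p = 0.000178 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 7618 genes). Spp1, a secreted matrix protein, was at 257 ± 80.8 and 781 ± 37.7 CPM (-1.61 ± 0.21, adjusted p = 0.0176 by the same test). These were the 2 genes called, and DESeq2 called 0 higher and 2 lower. At unadjusted p under 0.05, 249 were higher and 216 lower, 465 in all against 380.9 expected by chance. With equal numbers of cells per library neither was called, with Arg1 at -1.96 (adjusted p = 0.0624) and Spp1 at -1.97 (adjusted p = 0.443). Without S1, S2, S3 and S4 the calls numbered 162, 12, 217 and 20. Both genes lead cluster 3, so the border between clusters 3 and 7 could bear on their level in cluster 7, which was not tested. Arg1 also had lower estimates in cluster 2 (-2.30) and within cluster 3 (-1.16), and was not called there. Arg1 lies on chromosome 10 at 24915221 to 24927484 and Spp1 on chromosome 5 at 104435118 to 104441050.

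Interferon lists had positive medians in every macrophage cluster tested. In cluster 7 all 54 type I interferon-stimulated genes were positive (median 0.65, camera, adjusted p = 1.35e-23, and adjusted p = 0.525 with an estimated correlation), and 6 were higher adjusted over the list alone and 0 over all genes, led by Samd9l (1.62), Bst2 (0.69) and Stat2 (0.98). MHC class II presentation was at 0.32 there (adjusted p = 5.55e-07, and adjusted p = 0.525 with an estimated correlation), with 4 higher adjusted over the list alone (H2-Eb1 0.58, H2-Aa 0.51, Cd74 0.50, H2-Ab1 0.57) and 0 over all genes. Cell cycle genes in cluster 7 were at -0.53 (adjusted p = 2.35e-10, and adjusted p = 0.525 with an estimated correlation). In the monocyte-like cluster 4, the interferon list had a median of 0.67 (adjusted p = 2.94e-27, and adjusted p = 0.701 with an estimated correlation), and Isg20 (1.34 ± 0.26) and Oas1g (1.60 ± 0.36) were higher adjusted over the list alone, and 0 over all genes. Clusters 2 and 3 gave medians of 0.44 (adjusted p = 2.46e-15, and adjusted p = 0.760 with an estimated correlation) and 0.71 (adjusted p = 6.47e-17, and adjusted p = 0.647 with an estimated correlation). Without S2, cluster 2 was at 0.113 and its interferon list was not called (adjusted p = 0.112). Genes at unadjusted p under 0.05 numbered 277, 340 and 281 in clusters 4, 2 and 3. These were fewer than the 352.75, 472.15 and 371 expected by chance. By edgeR, 0 genes passed in cluster 4, with 145 higher and 132 lower unadjusted and 0 and 1 by DESeq2. The same test gave 0 in cluster 2 (174 and 166 unadjusted, 0 and 2 by DESeq2) and 0 in cluster 3 (146 and 135 unadjusted, 2 and 3 by DESeq2). Without S3 these counts were 376, 207 and 83, without S4 11, 3 and 9, without S2 0, 1 and 1, and without S1 0, 0 and 2.

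Cxcl10, an interferon-induced ligand of the chemokine receptor Cxcr3, was called higher in T cell-like cells. It was at 64.1 ± 1.67 CPM in Adar1-null and 20.1 ± 6.95 CPM in control libraries (log2 change 1.63 ± 0.20, adjusted p = 0.0265 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 9433 genes). AA467197, which encodes a small protein also known as Nmes1, fell from 408 ± 10.7 to 164 ± 28.8 CPM (-1.36 ± 0.13, adjusted p = 0.00392 by the same test). These were the only calls, and DESeq2 called 13 and 15. At unadjusted p under 0.05, 333 genes were higher and 337 lower, 670 in all against 471.65 expected by chance. Cxcl10 was not called by edgeR with doublets kept (1.68, adjusted p = 0.779), all barcodes kept (1.68, adjusted p = 0.756) or equal numbers of cells (1.58, adjusted p = 0.0895). Leaving out S1, S2, S3 and S4 gave 113, 70, 90 and 0 calls. Cxcl9, another Cxcr3 ligand, was at 57.9 ± 13.9 and 11.6 ± 4.70 CPM (2.29 ± 0.27, adjusted p = 0.0551). Macrophage-like cells held Cxcl10 at 842 ± 349 and 387 ± 154 CPM, so free RNA can add to the level in T cells. Cxcl10 lies on chromosome 5 at 92346638 to 92348889 and AA467197 on chromosome 2 at 122636986 to 122641191.

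In CD8 T cell-like cells alone, Il1r2, a decoy receptor for interleukin-1, fell from 74.2 ± 14.8 to 21.8 ± 4.68 CPM (-1.79 ± 0.20, adjusted p = 0.00908 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 8953 genes). Serpinb6b, a protease inhibitor, fell from 470 ± 64.6 to 248 ± 29.4 CPM (-0.96 ± 0.14, adjusted p = 0.0380 by the same test). The linker histone gene H1f0 fell from 116 ± 5.84 to 62.2 ± 8.90 CPM (-0.94 ± 0.14, adjusted p = 0.0380). AA467197 fell (-1.24 ± 0.13, adjusted p = 0.00813), and Cxcl10 rose from 10.5 ± 1.27 to 33.2 ± 0.406 CPM (1.62 ± 0.21, adjusted p = 0.0230). Rpl23a rose from 91.5 ± 6.23 to 185 ± 36.3 CPM (0.98 ± 0.15, adjusted p = 0.0380), and had higher estimates in every class. It shares 49.89% of its 3′ 25-base words with other genes, so a difference in how reads were assigned is not excluded. These were the 6 calls, and DESeq2 called 4 and 7. At unadjusted p under 0.05, 238 genes were higher and 325 lower, 563 in all against 447.65 expected by chance. Without S1, S2, S3 and S4 the calls numbered 13, 10, 17 and 0. Of killing genes, Gzmb (-0.26 ± 0.50), Prf1 (-0.64 ± 0.50) and Ifng (0.40 ± 0.53) did not pass. Gzmc, chosen after its values were seen, was at -2.27 and was not called. The list of cytotoxic effector genes had a median of -0.08 and a mean of -0.54. It was called by camera with the preset correlation only (adjusted p = 0.0057, and adjusted p = 0.636 with an estimated correlation). Mki67, a marker of dividing cells, was at 0.03 ± 0.12. Cluster 6 held most of these cells in each library (208, 205, 164 and 201).

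**Figure D3:**
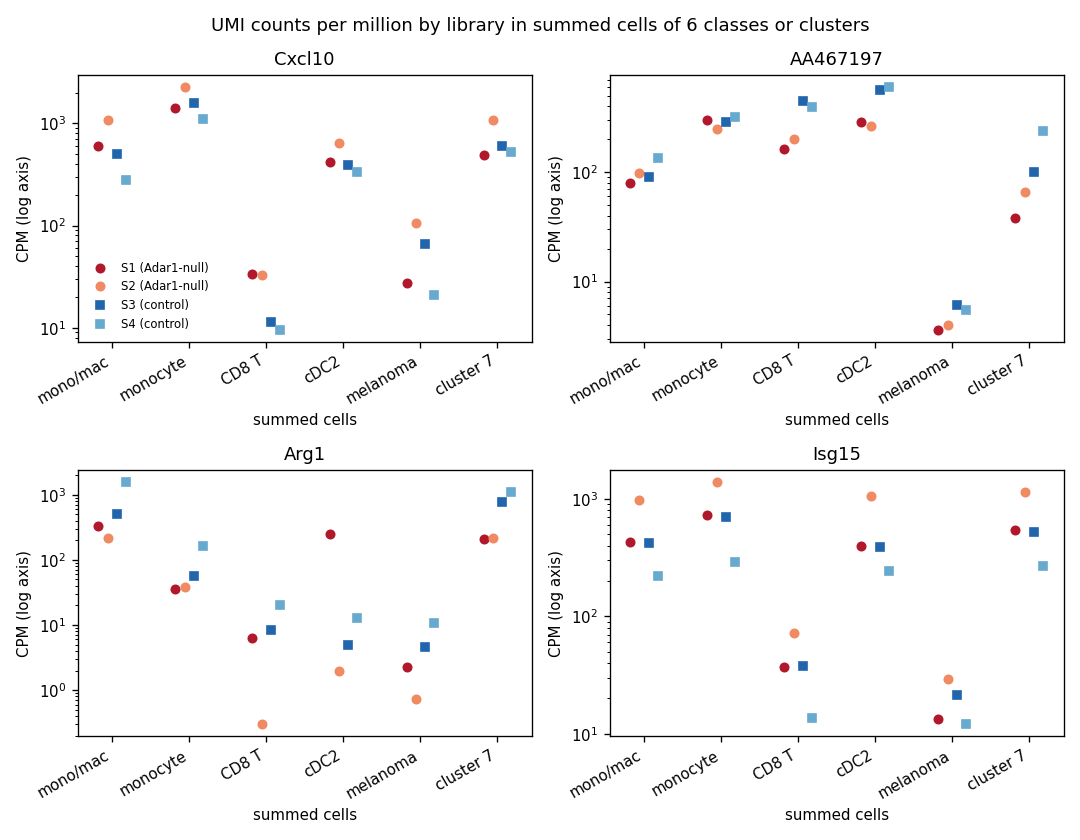
CPM (log axis) of Cxcl10, AA467197, Arg1 and Isg15 in the summed cells of 6 classes or clusters. Points are single libraries, circles S1 and S2 (Adar1-null) and squares S3 and S4 (control).

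Lists in T cell-like cells were called with camera's preset correlation only. Type I interferon-stimulated genes were positive for 47 of 48 (median 0.60, camera, adjusted p = 1.38e-23, and adjusted p = 0.547 with an estimated correlation), with 12 higher adjusted over the list alone, led by Oas3 (1.99), Irf7 (1.07 ± 0.19) and Ifit3 (1.44 ± 0.28), and 0 over all genes. In CD8 T cell-like cells the median was 0.45 (adjusted p = 2.44e-13, and adjusted p = 0.636 with an estimated correlation), with Oas3 (2.25) and Rtp4 (1.58) higher adjusted over the list alone, and 0 over all genes. Inhibitory receptor and exhaustion genes were at -0.22 in T cell-like cells (adjusted p = 0.00806, and adjusted p = 0.451 with an estimated correlation). Of these, Tnfrsf9 (-0.39), Havcr2 (-0.59), Cd244 (-0.71) and Pdcd1 (-0.41) were lower adjusted over the list alone, and 0 over all genes. In CD8 T cell-like cells alone this list was not called (-0.18, adjusted p = 0.0686, and adjusted p = 0.636 with an estimated correlation), and 0 members were lower adjusted over the list alone and 0 over all genes. Dissociation and immediate-early genes were at 0.22 (adjusted p = 9.38e-08, and adjusted p = 0.320 with an estimated correlation), with 5 higher adjusted over the list alone and 0 over all genes, led by Fos (0.69) and Nr4a1 (0.51). Cytotoxic effector genes were at -0.14 (adjusted p = 0.000255, and adjusted p = 0.422 with an estimated correlation), with Klrd1 (-0.47) lower adjusted over the list alone, and 0 over all genes. Their mean was lower than this median, at -0.57. MHC class II presentation was at 0.50 (adjusted p = 6.69e-07, and adjusted p = 0.547 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone and 0 over all genes, where free RNA from macrophages can contribute. Inflammatory macrophage genes were at 0.47 (camera, adjusted p = 9.38e-08, and adjusted p = 0.320 with an estimated correlation), with 6 higher adjusted over the list alone and 1 over all genes. In CD8 T cell-like cells, complement C1q and tissue-macrophage genes were at -0.36 with 3 of 20 positive (camera, adjusted p = 1.75e-05, and adjusted p = 0.636 with an estimated correlation). In naive and memory genes, not called (adjusted p = 0.0908, and adjusted p = 0.547 with an estimated correlation), Ccr7 (-0.75) was lower adjusted over the list alone, and 0 over all genes.

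Conventional dendritic cells 2 present antigen to CD4 T cells, and in conventional dendritic cell 2-like cells the interferon list again had a positive median. Its median was 0.58 (camera, adjusted p = 2.68e-13, and adjusted p = 0.754 with an estimated correlation), led by Eif2ak2 (1.44 ± 0.39), the double-stranded RNA-activated kinase PKR. Without S2 it was 0.127 and the list was not called (adjusted p = 0.0550). Of the interferon list, 0 members were higher adjusted over the list alone and 0 over all genes. Eif2ak2 was higher adjusted over the list of double-stranded RNA sensing genes alone, and 0 over all genes (median 0.58, adjusted p = 0.00184, and adjusted p = 0.754 with an estimated correlation). MHC class II presentation ran the other way, at -0.29 (adjusted p = 0.000842, and adjusted p = 0.850 with an estimated correlation). H2-Ob, a modulator of peptide loading, was at 34.0 ± 10.6 and 81.3 ± 1.31 CPM (-1.30 ± 0.30) and lower adjusted over the list alone, and 0 over all genes. Cd74 (-0.35 ± 0.24) and H2-Ab1 (-0.22 ± 0.23) did not pass. Lipid handling genes were at 0.46 (adjusted p = 0.000842, and adjusted p = 0.754 with an estimated correlation), led by Fdps (0.90). By edgeR, 94 genes were higher and 118 lower at unadjusted p under 0.05, 212 in all against 232.9 expected by chance. After adjustment 0 of 4658 genes passed edgeR's test, and DESeq2 called 0. The same test gave 10, 2, 80 and 20 calls without S1, S2, S3 and S4.

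Per the labels the deletion is in the melanoma cells, and their calls included macrophage transcripts and multi-copy genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 of 11393 genes were higher and 17 lower in melanoma-like cells, and DESeq2 called 1 and 1. Only 2 genes were called with doublets kept, 2 with all barcodes kept and 4 with equal numbers of cells. In simulated counts for these cells, 26 of 200 calls were false. The 548 genes with unadjusted p under 0.05 compare with 569.65 expected by chance. Leaving out S1, S2, S3 and S4 gave 49, 38, 141 and 100 calls. Phb, a mitochondrial chaperone gene, rose from 58.9 ± 5.68 to 81.2 ± 10.2 CPM (0.45 ± 0.09, adjusted p = 0.0114 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the pseudogene Rpl36-ps3 from 47.5 ± 6.18 to 63.9 ± 0.104 CPM (0.42 ± 0.09, adjusted p = 0.0128). Ccl8 fell from 117 ± 1.39 to 56.0 ± 10.3 CPM (-1.07 ± 0.11, adjusted p = 0.00357), C1qb from 63.2 ± 7.01 to 42.3 ± 6.12 CPM (-0.59 ± 0.10, adjusted p = 0.00805) and Ccl7 from 64.5 ± 7.13 to 49.8 ± 3.67 CPM (-0.38 ± 0.09, adjusted p = 0.0314). Gapdh, of glycolysis, fell by a log2 of 0.38 (adjusted p = 0.0364) and the ribosomal Rps2 by 0.31 (adjusted p = 0.0383). Of the 3′ 25-base words of Gapdh 53.92%, of Rps2 72.14% and of Phb 34.49% occur in other genes, so reads assigned differently are not excluded for these 3, nor for the pseudogene. Cluster 1 held most melanoma-like cells in each library (324, 264, 230 and 286).

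In melanoma-like cells the type I interferon medians of the libraries overlapped between the groups. The list had a median of 0.16 with 32 of 46 positive (camera, adjusted p = 0.00224, and adjusted p = 0.759 with an estimated correlation), and 0 passed adjusted over the list alone and 0 over all genes. Its centred medians were -0.27 and 0.42 in S1 and S2 and 0.35 and -0.52 in S3 and S4. Interferon-gamma-induced genes were at 0.15 (adjusted p = 0.000891, and adjusted p = 0.759 with an estimated correlation), with 1 higher adjusted over the list alone and 1 over all genes, and MHC class I presentation at 0.0256 (adjusted p = 0.00743, and adjusted p = 0.759 with an estimated correlation). None of these 3 lists kept its sign, with type I genes at -0.31 without S2 and 0.81 without S3, interferon-gamma-induced genes at -0.51 and 1.10, and MHC class I presentation at -0.32 without S4 and 0.80 without S3. Isg15 was at 0.36 ± 0.68, and the antigen presentation genes B2m and H2-K1 at 0.02 ± 0.43 and 0.01 ± 0.64. Cd274, which encodes PD-L1, was at -0.54 ± 0.92. Chemokines were at -0.59 (adjusted p = 1.28e-07, and adjusted p = 0.632 with an estimated correlation), with 4 lower adjusted over the list alone (Ccl8, Ccl7, Cxcl1, Cxcl16) and Ccl8 and Ccl7 over all genes. Unfolded protein response genes were at 0.04 (adjusted p = 0.0324, and adjusted p = 0.632 with an estimated correlation), and Asns (0.40) was higher adjusted over the list alone, and 0 over all genes. Dissociation and immediate-early genes were at -0.12 (adjusted p = 0.000335, and adjusted p = 0.632 with an estimated correlation), with 3 lower adjusted over the list alone and 2 over all genes, the reverse of T cell-like cells.

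Responses were then compared between classes. H2-Ab1 and Cd74, of MHC class II presentation to CD4 T cells, responded differently in clusters 2 and 7. H2-Ab1 had a log2 change of -0.26 in cluster 2 and 0.57 in cluster 7 (difference 0.82 ± 0.12, adjusted p = 6.42e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Cd74 -0.28 and 0.50 (difference 0.77 ± 0.11, adjusted p = 6.42e-05). AA467197 was at -1.36 in T cell-like cells and at -0.18 in the monocyte-like cluster, a difference of -1.17 ± 0.20 (adjusted p = 0.0406). Cxcl9 was at 2.29 in T cell-like and 0.72 in melanoma-like cells (difference -1.54 ± 0.30, adjusted p = 0.00734). For the same pair Gzmc, chosen after its values were seen, was at -2.38 and 0.15 (difference 2.55 ± 0.29, adjusted p = 1.46e-07 by the same test). Between macrophage-like and melanoma-like cells 0 of 12455 genes passed by edgeR (619 at unadjusted p under 0.05). Between the monocyte-like and the conventional dendritic cell 2-like cells 0 of 6789 passed (282 unadjusted). No list held with an estimated correlation in any of these comparisons.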

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

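The explanations by S4 alone, by S2 alone, by S2 and S4 together, by a shift between macrophage clusters and by ribosomal protein genes as a class, and the wider set of genes in melanoma-like cells, were chosen only after the results had been seen.

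Type I interferon-stimulated genes had higher medians in the Adar1-null T cell-like and myeloid units, and S2 and S4 together could set this difference, since S1 and S3 differed by a median of at most 0.20. In T cell-like cells 34 of 48 members were nevertheless higher in S1 than in S3, against 16 of 54 in cluster 3. The 8 units share cells, as CD8 T cell-like cells lie within T cell-like cells and clusters 2, 3, 4 and 7 within macrophage-like cells. Units called below were called with camera's preset correlation only. Without S4 alone the medians stayed between 0.26 and 0.46 and 8 of 8 units were still called, whereas without S2 alone they were between 0.11 and 0.31 with 6 of 8 called (not cluster 2 and conventional dendritic cell 2-like cells), which leaves S2 alone open. Free RNA is an unlikely sole source for the 7 members with more RNA in T cells than elsewhere, as all were positive (median 0.27). The whole list had a higher median in T cell-like cells, at 0.60, and free RNA stays open as a source for its other members there. A shift between macrophage clusters is not the sole source of the higher list median in macrophage-like cells, with medians of 0.44 to 0.71 within clusters 2, 3, 4 and 7. Clusters 5, 11 and 13 held too few cells in some library to be tested. A shift thus stays open as a part of the difference. The change may thus belong to the deletion or to S2 and S4, and 4 libraries do not tell these apart.

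Immune cell transcripts such as Ccl8 and C1qb were lower in Adar1-null melanoma-like cells, and free RNA from the other cells could explain this. The 6 transcripts had lower estimates in the other cells as well, though Ccl7 hardly so (-0.10). The median difference of the log2 changes was 0.05, with 4 of 6 within 0.5. Fcgrt (1.12) and Gzmf (0.54) lay beyond, as they fell more in the other cells. Macrophages attached to melanoma-like cells remain possible, since the tenth of 1239 cells with most of these 8796 UMIs held 29.87% of them against a Poisson share of 22.21%, a ratio of 1.34. In a wider set of 11 genes called lower, at least 5-fold higher in the other cells and not all immune transcripts, the values were -0.15 and 1.39.

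Multi-copy genes and pseudogenes were among the genes called higher in Adar1-null melanoma-like cells. Reads shared between copies stay open as the source. Of the 14 genes called higher, 13 had a transcript in the annotation searched, and in 10 of these (76.9%) at least 50% of 3′ 25-base words occurred in another gene. This decides nothing, as copies share sequence by definition. Of the 17 genes called lower, 3 passed the same bound, among them Gapdh and Rps2. A rise of ribosomal protein genes was to be judged by the median of those with unshared sequence. That median was -0.01, which speaks against a rise, but it rests on 3 genes, between -0.02 and 0.78, and decides little. As a class, the 79 ribosomal protein genes had an upper quartile of 0.05 and a median of 0.01, which speaks against a rise of the class. How reads were assigned, per library or by annotation, is not given in the sources used here.

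Differences in response between classes were found for several pairs, and the cause was not tested. Macrophage-like and T cell-like cells differed for 1 gene, Ccl17. Macrophage-like and CD8 T cell-like cells differed for 4, among them Gzmb (-1.23). In macrophage-like cells Gzmb was at only 12.6 ± 4.71 CPM in Adar1-null and 6.64 ± 1.88 CPM in control libraries (0.93). Free RNA from T cells can add it there. In CD8 T cell-like cells Gzmb was at 2778 ± 1437 and 3252 ± 615 CPM (-0.26). Macrophage-like and conventional dendritic cell 2-like cells differed for 12. The monocyte-like cluster differed from T cell-like cells for 4 genes, from CD8 T cell-like cells for 2 and from melanoma-like cells for 5. T cell-like cells differed from conventional dendritic cell 2-like cells for 3 and from melanoma-like cells for 29. CD8 T cell-like cells differed from conventional dendritic cell 2-like cells for 1 gene, Arg1, and from melanoma-like cells for 13. Arg1 was also called for T cell-like and for melanoma-like against conventional dendritic cell 2-like cells, in which its UMIs numbered 105, 1, 3 and 5 in S1 to S4. These calls of Arg1 thus rest on S1, and the gene was not tested within that class. Conventional dendritic cell 2-like and melanoma-like cells differed for 22. Among macrophages, clusters 2 and 3 differed for 3 genes, clusters 2 and 7 for 17 and clusters 3 and 7 for 1.

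H2-Ab1 responded by 0.82 more in cluster 7 than in cluster 2. For Cd74 this difference was 0.77. AA467197 responded by -1.17 in T cell-like less monocyte-like cells. Cxcl9 responded by -1.54 in melanoma-like less T cell-like cells. In the simulation of such differences between macrophage-like and CD8 T cell-like cells, 200 of 8628 genes were changed. Of genes moved by a log2 of 1, 22% were recovered, and of those moved by 2, 81%. False calls numbered 21. True calls can number at most 200, so the false share of the calls was more than the threshold allows.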

How the results depend on the processing

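Clustering with response genes, immune cells only and the largest melanoma-like cluster only were chosen only after the results had been seen, and all other alternatives were fixed before the data were examined. No paired analysis was possible because the deposited library names carry no replicate numbers, so the fits with the replicate as a block were not run. The share of cells with a UMI of a gene, with cells thinned to a fixed number of UMIs, was not run either, because no such share is reported. With 1 library left out, the lone library of its group is assumed to vary like the other group.

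In the whole infiltrate 0 genes were called, against 93 by DESeq2 (6 higher and 87 lower) and 1 with no filter on low counts. Leaving out S1, S2 or S4 gave 0 and leaving out S3 gave 118. With immune cells only, chosen later, the count stayed at 0. The 8 lists called became 0 with an estimated correlation and 0 with fry, and 10, 15, 16 and 10 without S1, S2, S3 and S4. The type I interferon list had a median of -0.15 without S2 and 0.62 without S3, so its sign depended on S2.

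Monocyte- or macrophage-like cells gave 0 genes, against 21 by DESeq2 and 8 with no filter. Without S1, S2 or S4 the count was 0 and without S3 it was 86. The 13 lists called became 0 with an estimated correlation and 0 with fry, and between 9 and 17 with 1 library left out. Cell cycle genes had a median of -0.39 without S4 and 0.16 without S3. Oxidative phosphorylation genes were at -0.0619 without S4 and 0.29 without S3.

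The monocyte-like cluster gave 0 genes, against 1 by DESeq2, 45 with no filter, 1 with doublets kept, 1 with all barcodes kept and 1 at a Leiden resolution of 0.5. The counts without S1, S2, S3 and S4 were 0, 0, 376 and 11. Its 9 lists became 0 with an estimated correlation and 0 with fry, and 10, 2, 15 and 2 without S1, S2, S3 and S4. The interferon-gamma list was at -0.0517 without S2 and 1.04 without S3. MHC class II presentation was at -0.0681 without S4 and 0.73 without S3. Inflammatory macrophage genes were at -0.0517 without S2 and 0.40 without S1. Hypoxia and glycolysis genes were at -0.31 without S3 and 0.0315 without S4.

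T cell-like cells gave 2 genes, against 4 with RLE size factors, 28 by DESeq2, 179 with no filter, 4 with equal numbers of cells and 4 when clustered with response genes. Cxcl10 lost its call with doublets kept, all barcodes kept and equal numbers of cells, at log2 changes of 1.68, 1.68 and 1.58. AA467197 kept its call in these settings. Leaving out S1, S2, S3 and S4 gave 113, 70, 90 and 0, and Cxcl10 and AA467197 both lost their call without S4. Their log2 changes there were 1.31 and -1.32 (adjusted p = 0.0820 for both), so the lost calls do not show that S4 sets the changes. The 13 lists became 0 with an estimated correlation and 0 with fry, and between 11 and 13 with 1 library left out. MHC class I presentation was at -0.0559 without S4 and 0.28 without S3. Hypoxia and glycolysis genes were at -0.20 without S2 and 0.0631 without S1. Lipid handling genes had a median of 0.0464 without S1, where the test pointed down, and 0.33 without S4.

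CD8 T cell-like cells gave 6 genes, against 11 by DESeq2, 101 with no filter and 13 with equal numbers of cells. Without S1, S2, S3 and S4 the counts were 13, 10, 17 and 0, and all 6 genes lost their call without S4. There AA467197 was at -1.31, Cxcl10 at 1.51, Il1r2 at -1.55, Serpinb6b at -0.80, H1f0 at -0.98 and Rpl23a at 0.93, not far from their main values. H1f0 lost its call whichever library was left out, at -1.08 without S1 and -0.79 without S2. AA467197, Cxcl10 and Serpinb6b also lost theirs without S1, Rpl23a without S2, and Cxcl10 and Rpl23a without S3. The 10 lists became 0 with an estimated correlation and 0 with fry. The interferon-gamma list was at -0.0713 without S2 and 0.43 without S3. MHC class I presentation was at -0.0582 without S4 and 0.26 without S3. MHC class II presentation was at -0.0115 without S1 and 0.71 without S2.

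Conventional dendritic cell 2-like cells gave 0 genes, and 14 with no filter. It was 10, 2, 80 and 20 without S1, S2, S3 and S4. The 8 lists became 0 with an estimated correlation and 0 with fry, and 7, 7, 13 and 11 without S1, S2, S3 and S4. Interferon-gamma-induced genes were at -0.29 without S2 and 0.61 without S1. MHC class I presentation was at -0.0666 without S2 and 0.36 without S1.

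Melanoma-like cells gave 31 genes, against 2 by DESeq2, 94 with no filter, 2 with doublets kept, 2 with all barcodes kept and 4 with equal numbers of cells. The largest melanoma cluster only, chosen later, gave 8. With S1, S2, S3 and S4 left out there were 49, 38, 141 and 100. Mgll kept its call with doublets kept. The 10 lists became 0 with an estimated correlation and 0 with fry, and 12, 4, 15 and 11 without S1, S2, S3 and S4. The type I interferon list was at -0.31 without S2 and 0.81 without S3. For interferon-gamma-induced genes the median was -0.51 without S2 and 1.10 without S3. MHC class I presentation was at -0.32 without S4 and 0.80 without S3.

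Cluster 2 gave 0 genes, against 2 by DESeq2 and 70 with no filter. Without S1, S2, S3 and S4 the counts were 0, 1, 207 and 3. Its 10 lists became 0 with an estimated correlation and 0 with fry, and 11, 1, 15 and 7 with S1, S2, S3 and S4 left out. Interferon-gamma-induced genes were at -0.19 without S2 and 0.62 without S3. MHC class I presentation was at -0.0317 without S2 and 0.38 without S3. MHC class II presentation was at -0.54 without S4 and 0.14 without S3.

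Cluster 3 gave 0 genes, against 5 by DESeq2 and 47 with no filter. With S1, S2, S3 and S4 left out the counts were 2, 1, 83 and 9. Its 10 lists became 0 with an estimated correlation and 0 with fry, and 16, 6, 10 and 7 without S1, S2, S3 and S4. For interferon-gamma-induced genes the median was -0.31 without S2 and 1.23 without S3. MHC class I presentation was at -0.0586 without S2 and 0.70 without S3. Inflammatory macrophage genes were at -0.17 without S2 and 0.76 without S1. Dissociation and immediate-early genes had a median of 0.00989 without S2, where the test pointed down, and 0.33 without S1.

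Cluster 7 gave 2 genes, against 78 with no filter and 0 with equal numbers of cells. Without S1, S2, S3 and S4 it gave 162, 12, 217 and 20. The 11 lists became 0 with an estimated correlation and 0 with fry, and 10, 6, 11 and 10 without S1, S2, S3 and S4. Interferon-gamma-induced genes were at -0.0782 without S2 and 0.73 without S1. Inflammatory macrophage genes were at -0.10 without S2 and 0.38 without S1.

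All 95 shares of classes, T cell subsets and myeloid clusters refitted under alternatives other than leaving out a library kept their side, among them those with TMM on cell numbers and a denominator of immune cells. Natural killer cell-like cells had a log2 ratio of -0.38 without S4 and 1.94 without S3. Conventional dendritic cell 2-like cells were at -0.17 without S4 and 0.81 without S3, endothelial-like cells at -0.75 without S4 and 0.30 without S3, and fibroblast-like cells at -0.85 without S2 and 0.23 without S1. The unnamed cluster 12 was at -3.91 without S1 and -1.63 without S4, and at -3.83 without S3, where it was called (adjusted p = 0.00505). The regulatory T cell-like share was at 0.35 without S1 and 0.77 without S2, where it was called (adjusted p = 0.0443).

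Among monocytes, macrophages and dendritic cells, cluster 2 was at -0.75 without S1 and 0.37 without S2. Cluster 5 was at -3.69 without S1 and -1.69 without S4, and cluster 12 at -3.62 without S1 and -1.47 without S4. Cluster 9 was at -0.0137 without S4 and 1.14 without S3. Cluster 11 was at 0.39 without S2 and 3.92 without S3. Cluster 13 was at -0.87 without S1 and 0.89 without S3, and cluster 15 at -0.35 without S4 and 0.04 without S3. Clusters 5, 11 and 12 were called without S3 only.

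Of the 41 calls of a gene in a class, 29 were not made by DESeq2, 30 were lost with doublets kept, 30 with all barcodes kept and 30 with equal numbers of cells. Without S1, S2, S3 and S4, 19, 20, 10 and 22 were lost. No called gene changed its sign.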

Other observations

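Idi1 and Fdps, 2 sterol synthesis genes of the lipid handling list, had higher estimates in Adar1-null myeloid cells. Sterol synthesis was not tested as a list. In monocyte- or macrophage-like cells Idi1 was at 17.4 ± 0.707 and 8.21 ± 2.61 CPM (log2 change 1.09 ± 0.25) and Fdps at 44.1 ± 3.18 and 20.9 ± 9.26 CPM (1.08 ± 0.31). Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.888 for both). In the monocyte-like cluster Fdps was at 0.80 and Idi1 at 0.81.

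AA467197 had lower estimates in every class and cluster tested, and passed the test only in T cell-like and CD8 T cell-like cells. It was at 163 and 201 CPM against 443 and 393 CPM in CD8 T cell-like cells, and at 289 and 266 against 566 and 601 CPM in conventional dendritic cell 2-like cells. Monocyte-like cells gave 297 and 247 against 285 and 322 CPM. The log2 change was -1.56 in cluster 7, -1.22 in cluster 2, -0.67 in cluster 3 and -0.60 in melanoma-like cells. The gene is induced in inflammation, and its role in T cells was not tested.

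Haemoglobin RNA marked S4, and was chosen after its values were seen. Hbb-bs was at 0, 0.301, 1.39 and 518 CPM in S1 to S4 of the whole infiltrate and at 818 CPM in melanoma-like and 1009 CPM in cluster 3 cells of S4. In S4 it was far lower in T cell-like (33.9 CPM), monocyte-like (46.7 CPM), conventional dendritic cell 2-like (53.9 CPM) and cluster 7 cells (53.8 CPM). The cause was not tested.

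Multi-copy genes, also chosen after their values were seen, had estimates of the same sign across classes. Rpl23a was at 1.06 in the whole infiltrate, 0.99 in macrophage-like, 0.92 in T cell-like and 1.05 in melanoma-like cells. Rpl9 was at 0.66, 0.58, 0.57 and 0.75 in the same order. Gapdh was at -0.48, -0.29, -0.53 and -0.38, and Rps2 at -0.22, -0.24, -0.31 and -0.31.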
